A study of Oryza sativa Japonica Group with 48 samples.

How the data were processed

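The data were 48 RNA sequencing libraries of rice seedlings grown in hydroponics for 14 days, per the labels, from CSR28 and IR28, roots and shoots, 6 h and 54 h, control and 150 mM NaCl, with 3 biological replicates each. Per the labels the libraries were read as single ends of 150 bases with 16 libraries per lane, and which libraries shared a lane is not given. The labels' extraction text speaks of mature leaves, while the sample labels give root or shoot, and the sample labels were used. Per the submitters' processing notes base calls came from CASAVA, transcripts were quantified with kallisto 0.45.0 and tested with sleuth 0.28.1. The genome build and annotation release were not given in the sources used here. The deposited file holds 66338 transcript models with locus identifiers and descriptions, and no chromosome positions.

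Per the file headers the values are estimated counts. Within each library most values were multiples of a step that differed between libraries, from 0.383 to 2.17. The signal values were therefore read as estimated counts that the authors divided by a size factor per library before they were deposited, and not as counts. The deposited TPM signal columns were likewise divided by a size factor, with totals of 0.712 to 1.84 M per library, and are called scaled TPM here. The deposited mean TPM per group is a summary of these columns, and 16 further columns, the deposited SD per group, were not used. The deposited q-value is the authors' adjusted p-value of salt against control per genotype, tissue and time, left blank where the authors did not test. The deposited b is the authors' effect size on a natural log scale. These last columns were read for the range of results and not tested again.

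Counted in steps, 60.3% to 68.5% of transcripts and 85.2% to 91.1% of gene sums lay within 0.01 reads of a whole number. This was judged too few for a count test, and rounded sums were not tested. The signal was tested instead. Transcripts were summed to 55803 genes, 49344 of them with 1 model. Genes with a value of at least 1 in at least 3 libraries of a tissue were tested, 33231 in roots and 33606 in shoots. Values were log2 transformed after adding 0.5 and fitted with limma 3.58.1 (linear models with a variance trend) in R 4.3.3, with 1 fit per tissue over its 24 libraries and 8 groups. Contrasts were salt against control within genotype and time, the difference of that response between genotypes, its difference between times, and CSR28 against IR28 in control plants. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Tables were read with data.table (1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

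Gene groups were 27 lists fixed before any result was seen. Lists named by identifier, from general knowledge of rice gene names, were abscisic acid synthesis and breakdown, clade A protein phosphatases, LEA and dehydrin genes, stress transcription factors, sodium and potassium transport, osmolyte genes, antioxidant genes, aquaporins, jasmonate genes, nitrogen genes, iron uptake, cellulose synthases, heat shock, chlorophyll breakdown, the clock, photosynthesis, root-specific genes and single salt markers. Another 9 were taken from the descriptions in the deposited table: cytosolic ribosomal proteins, histones, expansins, class III peroxidases, glutathione S-transferases, WRKY factors, LEA or dehydrin by keyword, small heat shock proteins and cyclins. The gene YSL15 was left out of the iron list, because the description of its locus is that of a transposon protein. Lists were tested with limma camera at a preset correlation of 0.01 and again with a correlation estimated from the data, adjusted over the lists of each contrast. The counts of members that passed are given over all genes and adjusted over the list alone.

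Genes were named by rule: the 5 largest passing changes per direction for salt responses and for genotype differences of the response, and 3 per direction for the other contrasts, with a mean of at least 5 scaled TPM in a group and an informative description. For salt responses the groups also had to be fully apart. Fixed markers and the members of each list with the smallest p-values were added. Fold was not given against a group listed at 0.

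Whether replicates with the same number were paired was checked by correlating the residuals of a fit. In 1 of 12 comparisons, CSR28 roots at 54 h with salt against control, every same-number correlation was over 0.1 (0.51, 0.31 and 0.46), and over all comparisons the values ran from -0.23 to 0.51. A fit with the replicate number as a block gave 6870 genes there instead of 6668. The unpaired fit was kept for all contrasts.

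The procedure was tested on simulated data in which 200 genes with a mean value of at least 20 were changed. Of genes changed 1.5-fold, 2-fold and 4-fold it recovered 3%, 58.2% and 98.5% in roots and 38.8%, 70.1% and 97% in shoots. For differences between genotypes it recovered 3%, 22.4% and 80.3% in roots and 9%, 50.7% and 89.4% in shoots. Among unchanged genes 8 were called in roots and 5 in shoots. These shares need not hold where more genes change.

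Library checks used correlation with sister libraries, trends with transcript length and the spread of residuals. CSR28 root 54 h control replicate 1 correlated with its sisters at 0.901 and 0.871 and its residuals fell with transcript length (rank correlation -0.43, and 0.45 for replicate 3). IR28 root 54 h salt replicate 2 stood at 0.94 and 0.924 (-0.42 with length) and CSR28 shoot 6 h control replicate 1 at 0.956 and 0.937 (-0.57 with length, and 0.58 for replicate 3). CSR28 root 54 h salt replicate 1 also had a trend of -0.41. Taken against sister libraries, a trend pushes theirs the other way by construction. No library was left out of the tests.

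The alternatives run were median-of-ratios scaling, no variance trend, no filter beyond a total of 1, a filter of 1 per M in 12 libraries, a pseudocount of 1, scaled TPM, fits on only the groups compared, a replicate block, a 2-fold minimum, transcript-level tests, leaving out each library in turn, and camera with an estimated correlation. Weights per library and leaving out the libraries that stood apart were added after the data had been seen. The authors' deposited q-values under 0.05 numbered 14149 and 1347 transcripts in CSR28 roots at 6 h and 54 h, 5927 and 8215 in IR28 roots, 11875 and 22918 in CSR28 shoots, and 11053 and 24262 in IR28 shoots. The supplied gene reference table could not be joined to the locus identifiers and was not used.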

Results

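RNA levels were measured by sequencing in roots and shoots of rice seedlings of a pair of genotypes, CSR28, labelled salt-tolerant, and IR28, labelled salt-sensitive. After 14 days in hydroponics plants were given 150 mM NaCl or control solution for 6 h or 54 h, with 3 biological replicates in each of the 16 groups, 48 libraries in all. Read depth, worked out from the value that 1 read is worth in each library, ran from 6.30 to 32.4 M reads in roots (median 12.1 M) and from 12.4 to 30.4 M reads in shoots (median 16.4 M). In roots 33231 genes and in shoots 33606 genes had enough signal to be tested. Fold values below are log2 differences of values with 0.5 added, which understates the change of weakly expressed genes. Expression levels are scaled TPM, given as mean ± SD of 3 libraries, and the p-values rest on replicates that the labels call biological. Values of near-identical gene copies, such as the RAB16 dehydrins, the lipid transfer proteins and the BURP proteins, are uncertain, because reads shared between copies are divided by the quantification program.

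**Figure D1:**
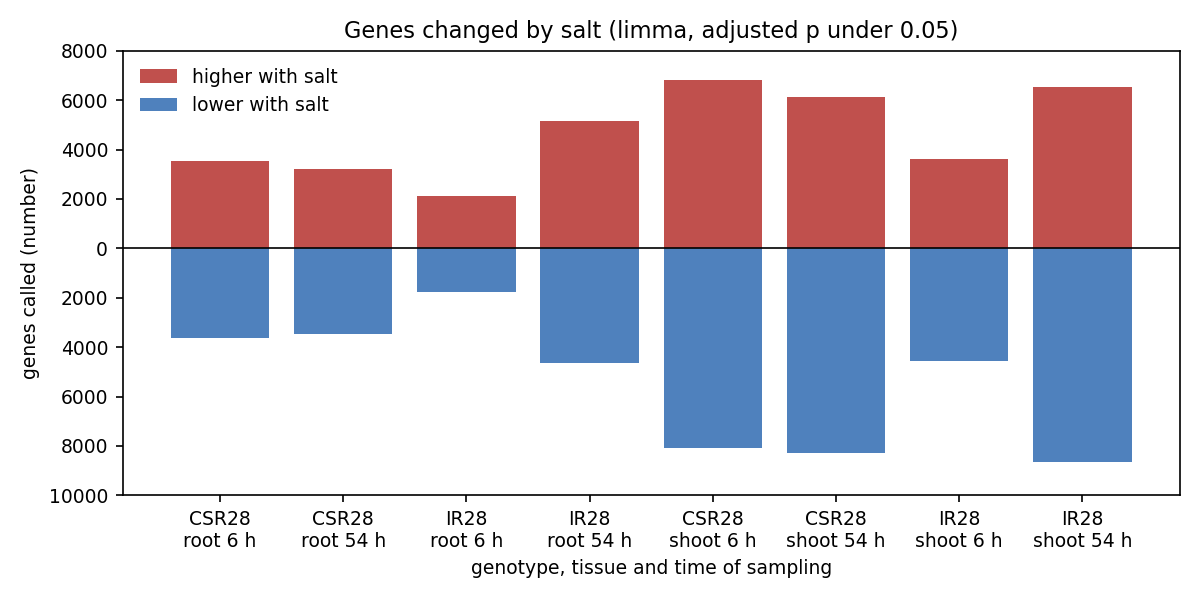
Genes with a salt response at adjusted p < 0.05 in each genotype, tissue and time (number of genes, bars above 0 for higher with salt, bars below 0 for lower with salt, 3 libraries per group). Shoots had more calls than roots of the same genotype and time, but spreads were set per tissue, so tissues should not be ranked.

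In CSR28 roots after 6 h of salt, the dehydrin gene RAB16D, whose product protects cells that lose water, rose from a control level of 0.564 ± 0.293 to 84.0 ± 8.16 scaled TPM (log2 fold 7.13, SE 0.26, adjusted p = 3.81e-13, n = 3 per group). The iron transporter gene IRT1 rose to 24.6 ± 1.32 from 0.438 ± 0.0539 (log2 fold 5.74, SE 0.23, adjusted p = 9.71e-13). The lectin gene SalT, a classical salt marker, stood at 292 ± 32.8 against 42.4 ± 2.98 (log2 fold 2.76, SE 0.32, adjusted p = 1.70e-06). The aquaporin gene TIP2;1, which encodes a water channel of the vacuole, fell to 86.0 ± 10.9 from 598 ± 99.1 (log2 fold -2.81, SE 0.24, adjusted p = 4.15e-08), and the nitrite reductase gene NiR to 30.4 ± 7.15 from 290 ± 29.9 (log2 fold -3.29, SE 0.19, adjusted p = 3.66e-10).

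Of the 9 tested LEA and dehydrin genes, 7 rose in these roots, 1 fell and 1 did not pass (7 higher and 1 lower adjusted over the list alone, below list-adjusted), with a median log2 fold of 3.73 (limma camera adjusted p = 3.05e-08, and 0.0425 with an estimated correlation). RAB16A (4.84, SE 0.45), WSI18 (3.73, SE 0.30) and LEA3-1 (3.42, SE 0.33) were among the higher ones. Of 23 stress transcription factors 14 rose and 0 fell (14 and 0 list-adjusted, camera adjusted p = 1.16e-07, and 0.0229 with an estimated correlation). HOX24 stood at 3.69, SE 0.40, DREB1A at 3.39, SE 0.45 and NAC6 at 1.91, SE 0.14. Of the clade A protein phosphatases, which turn off abscisic acid signalling, 5 of 9 rose (6 higher and 1 lower list-adjusted), including PP2C49 at 2.52, SE 0.27 (camera adjusted p = 0.00109, and 0.121 with an estimated correlation). Abscisic acid synthesis and breakdown genes gave 3 higher of 7 (4 list-adjusted), among them NCED4 at 2.33, SE 0.51 and ABA8ox2 at 2.93, SE 0.23 (camera adjusted p = 0.00276, and 0.0999 with an estimated correlation).

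In CSR28 roots at 6 h all 6 tested cellulose synthase genes fell (6 list-adjusted), including CESA7 at -2.31, SE 0.20 and CESA9 at -2.29, SE 0.20 (camera adjusted p = 1.66e-07, and 0.0433 with an estimated correlation). Aquaporins gave 10 lower of 14 (10 list-adjusted, median -0.88), with PIP2;5 at -2.40, SE 0.21 and PIP2;4 at -1.52, SE 0.18 (camera adjusted p = 1.99e-08, and 0.0433 with an estimated correlation). For nitrogen genes 7 of 11 fell (8 list-adjusted), among them the nitrate reductase gene NIA1 at -3.01, SE 0.27 (camera adjusted p = 6.67e-07, and 0.130 with an estimated correlation). Class III peroxidases gave 12 higher and 63 lower of 133 (15 and 67 list-adjusted, camera adjusted p = 6.62e-11, and 0.0719 with an estimated correlation). Histones gave 2 and 19 of 56 (3 and 23 list-adjusted, adjusted p = 5.54e-05, and 0.432 with an estimated correlation). Cyclins gave 3 and 15 of 58 (3 and 15 list-adjusted, adjusted p = 0.00245, and 0.101 with an estimated correlation). The sodium transporter gene HKT2;1 (-2.42, SE 0.25) and the potassium transporter gene HAK1 (-1.60, SE 0.31) also fell. The sodium and potassium transport list as a whole had a median of 0.08 with a test direction of lower (adjusted p = 0.811).

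Among genes with the largest changes in CSR28 roots at 6 h, taken from those whose 3 salt and 3 control libraries did not overlap, were the sugar transporter family gene LOC_Os03g22590 (MtN3) at 8.70, SE 0.47, the ent-kaurene synthase LOC_Os02g36210 at 6.61, SE 0.83 and the pathogenesis-related genes PBZ1 at 5.74, SE 0.45 and RSOsPR10 at 4.10, SE 0.48. The jasmonate synthesis gene AOS2 reached 4.28, SE 0.32. On the lower side stood the cysteine synthase LOC_Os06g36850 at -6.59, SE 0.61, the auxin-induced OsSAUR3 (LOC_Os01g70050) at -4.98, SE 0.42 and the root cortex gene RCC3 at -2.11, SE 0.21. With limma, 7187 genes passed adjusted p < 0.05, 3544 higher and 3643 lower, and 4738 of them changed at least 2-fold. The 3 salt libraries lay fully apart from the 3 control libraries in 7075 of these genes and in 44.7% of all tested genes, where chance alone gives 10%, here and in the shares below. Without the pair of root libraries that stood apart at 54 h, 11006 genes passed.

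After 54 h CSR28 roots held RAB16D at 226 ± 19.6 against 0.792 ± 0.205 (log2 fold 8.05, SE 0.26, adjusted p = 3.41e-14, n = 3 per group). NCED4, which encodes the enzyme that opens abscisic acid synthesis, rose from 0.691 ± 0.482 to 15.03 ± 4.21 (log2 fold 4.81, SE 0.51, adjusted p = 7.91e-07). SalT stood at 296 ± 62.1 against 121 ± 70.5 (log2 fold 1.41, SE 0.32, adjusted p = 0.00296), but its call was lost when only these groups were fitted (adjusted p = 0.203). The control group with its SD of 70.5 holds a library that stood apart. TIP2;1 fell (log2 fold -3.33, SE 0.24, adjusted p = 7.81e-09), as did the root gene RCC3 (log2 fold -2.29, SE 0.21, adjusted p = 1.36e-07).

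In CSR28 roots at 54 h LEA and dehydrin genes rose in 8 of 9 (8 list-adjusted, median 4.84, camera adjusted p = 2.91e-13, and 0.00488 with an estimated correlation), including RAB16C (7.52, SE 0.59), RAB16A (5.86, SE 0.45) and LEA3-1 (4.59, SE 0.33). Abscisic acid synthesis and breakdown genes rose in 6 of 7 (7 list-adjusted, adjusted p = 2.25e-07, and 0.00732 with an estimated correlation), with NCED3 at 2.47, SE 0.43. Protein phosphatases rose in 6 of 9 (6 list-adjusted, adjusted p = 6.12e-07, and 0.0351 with an estimated correlation), with PP2C30 at 3.74, SE 0.30. Stress transcription factors rose in 13 of 23 (15 list-adjusted, adjusted p = 2.51e-09, and 0.00488 with an estimated correlation), with HOX24 at 4.73, SE 0.40, ZFP182 at 2.95, SE 0.32 and NAC10 at 2.31, SE 0.22. All 6 chlorophyll breakdown genes rose (6 list-adjusted), NYC1 by 2.18, SE 0.30 (camera adjusted p = 9.30e-05, and 0.0655 with an estimated correlation).

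Cellulose synthases fell in 5 of 6 at 54 h (5 list-adjusted), with CESA9 at -2.23, SE 0.20 (camera adjusted p = 1.51e-06, and 0.0634 with an estimated correlation). Photosynthesis genes, much lower in roots than in shoots, fell in 10 of 19 (14 list-adjusted, median -0.70, camera adjusted p = 3.02e-06, and 0.339 with an estimated correlation). Histones gave 1 higher and 31 lower of 56 (2 and 32 list-adjusted, adjusted p = 5.07e-10, and 0.331 with an estimated correlation). WRKY factors gave 29 higher and 3 lower of 100 (35 and 6 list-adjusted, adjusted p = 2.75e-06, and 0.0655 with an estimated correlation). Other large steps were in the P450 gene LOC_Os01g43740 (7.14, SE 1.45), the lipid transfer gene LOC_Os10g40470 (-7.54, SE 0.53) and the expansin gene LOC_Os06g01920 (-5.85, SE 0.79). With limma 6668 genes passed, 3216 higher and 3452 lower, 4329 of them by at least 2-fold. Fitted on only these groups 1533 passed. SalT, NCED3 (adjusted p = 0.0638), LOC_Os01g43740 (0.146), LOC_Os06g01920 (0.0502) and chlorophyll genes NYC1 (0.0691), SGR (0.283), PAO (0.181) and NAP (0.0915) did not. Groups lay fully apart in 6090 of the 6668 and in 26.6% of tested genes. Control replicate 1 correlated with its sisters at 0.901 and 0.871. Without it and IR28 salt replicate 2 of the same time 7696 genes passed.

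IR28 roots at 6 h carried a far larger SalT signal with salt, 1140 ± 225 against 16.4 ± 1.15 scaled TPM (log2 fold 6.08, SE 0.32, adjusted p = 6.51e-11, n = 3 per group). RAB16D rose from 0.486 ± 0.0976 to 26.5 ± 1.74 (log2 fold 5.58, SE 0.26, adjusted p = 1.53e-11) and IRT1 from 0.631 ± 0.0713 to 13.3 ± 1.52 (log2 fold 4.34, SE 0.23, adjusted p = 6.51e-11). The lipid transfer gene LOC_Os10g36090 (LTPL156) had the largest step, with 249 ± 27.0 against 0.0973 ± 0.169 (log2 fold 10.04, SE 0.87, adjusted p = 8.81e-08). An actin gene, LOC_Os12g06660, fell to 6.70 ± 0.307 from 203 ± 43.9 (log2 fold -4.91, SE 0.23, adjusted p = 1.53e-11).

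By groups, IR28 roots at 6 h showed 6 of 9 LEA and dehydrin genes higher (8 list-adjusted), with RAB16A at 3.64, SE 0.45 (camera adjusted p = 4.52e-08, and 0.0847 with an estimated correlation). Protein phosphatases were higher in 6 of 9 (6 higher and 1 lower list-adjusted), PP2C49 at 2.65, SE 0.27 (camera adjusted p = 8.38e-06, and 0.0857 with an estimated correlation). Expansins, which loosen cell walls, were higher in 19 and lower in 1 of 55 (19 and 3 list-adjusted, adjusted p = 5.12e-05, and 0.193 with an estimated correlation). Glutathione S-transferases were higher in 20 and lower in 5 of 81 (29 and 5 list-adjusted, adjusted p = 6.73e-06, and 0.234 with an estimated correlation). Of aquaporins 5 of 14 fell (7 list-adjusted), including PIP2;5 at -2.69, SE 0.21 (camera adjusted p = 7.41e-07, and 0.0857 with an estimated correlation). Nitrogen genes fell in 5 of 11 (6 list-adjusted), NiR at -2.96, SE 0.19 and NIA1 at -2.73, SE 0.27 (camera adjusted p = 2.23e-06, and 0.193 with an estimated correlation). The root-specific gene list fell in 4 of 7 (4 list-adjusted), CASP1 at -1.49, SE 0.18 (adjusted p = 1.08e-04, and 0.0895 with an estimated correlation). For jasmonate genes 4 of 10 rose (4 higher and 1 lower list-adjusted) although the list median was -0.14, its mean 0.43 and its test direction higher (adjusted p = 0.132).

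Further single genes that rose in IR28 roots at 6 h were the proline synthesis gene P5CS2 (2.87, SE 0.34), the catalase gene CATA (1.66, SE 0.30), AOS2 (4.27, SE 0.32), PBZ1 (4.36, SE 0.45), HOX24 (3.24, SE 0.40) and the terpene synthase LOC_Os12g30824 (7.70, SE 0.98). The sodium transporter gene HKT2;1 (-2.17, SE 0.25), the potassium transporter gene HAK1 (-1.67, SE 0.31), the cysteine synthase LOC_Os06g36850 (-5.46, SE 0.61) and OsSAUR3 (-4.78, SE 0.42) fell. With limma 3906 genes passed, 2129 higher and 1777 lower, and 2722 changed at least 2-fold. Salt and control libraries did not mix in 3855 of the passing genes and 35.6% of tested genes. Without the libraries that stood apart at 54 h 6464 genes passed.

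In IR28 roots at 54 h RAB16A rose from 0.226 ± 0.126 to 231 ± 53.0 scaled TPM (log2 fold 9.84, SE 0.45, adjusted p = 3.64e-12, n = 3 per group), and SalT from 28.1 ± 5.88 to 1321 ± 536 (log2 fold 5.57, SE 0.32, adjusted p = 8.24e-11). The water channel gene TIP2;1 fell from 450 ± 65.1 to 33.4 ± 5.55 (log2 fold -3.68, SE 0.24, adjusted p = 5.14e-10). HKT1;5, which takes sodium out of the xylem, fell from 12.7 ± 1.19 to 4.68 ± 1.81 (log2 fold -1.45, SE 0.30, adjusted p = 8.68e-04), and the test of a genotype difference in this response gave adjusted p = 0.416. HKT1;1 rose (2.17, SE 0.27) and the potassium channel gene AKT1 fell (-1.96, SE 0.30).

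All 9 LEA and dehydrin genes rose in IR28 roots at 54 h (9 list-adjusted), with a median of 6.19 and LEA3-1 at 6.19, SE 0.33 (camera adjusted p = 8.69e-16, and 0.00212 with an estimated correlation). Protein phosphatases rose in 8 of 9 (8 list-adjusted), PP2C30 at 5.55, SE 0.30 and PP2C68 at 4.84, SE 0.26 (adjusted p = 1.58e-10, and 0.00689 with an estimated correlation). Abscisic acid synthesis and breakdown genes rose in 5 of 7 (5 list-adjusted), ABA8ox3 at 6.12, SE 0.66 (adjusted p = 8.55e-06, and 0.0173 with an estimated correlation). Stress transcription factors gave 16 higher and 1 lower of 23 (18 and 1 list-adjusted), HOX24 at 8.41, SE 0.40 and ZFP182 at 4.51, SE 0.32 (adjusted p = 2.63e-11, and 0.00212 with an estimated correlation). Jasmonate genes rose in 7 of 10 (7 list-adjusted), JAZ11 at 3.30, SE 0.28 (adjusted p = 4.90e-04, and 0.153 with an estimated correlation). All 6 cellulose synthases fell (6 list-adjusted), CESA4 at -2.52, SE 0.17 (adjusted p = 4.15e-08, and 0.0226 with an estimated correlation). Nitrogen genes fell in 10 of 11 (10 list-adjusted), the nitrate transporter NRT2;1 at -3.35, SE 0.49, a gene whose values are identical to those of its copy NRT2;2 (adjusted p = 2.60e-08, and 0.0940 with an estimated correlation). Glutathione S-transferases gave 41 higher and 5 lower of 81 (44 and 6 list-adjusted, adjusted p = 4.57e-07, and 0.159 with an estimated correlation).

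The peroxidase genes LOC_Os07g31610 (-8.29, SE 0.59) and LOC_Os07g44460 (-7.54, SE 0.75) and the expansin gene LOC_Os06g01920 (-7.31, SE 0.79) had the deepest falls of IR28 roots at 54 h. RAB16D (9.28, SE 0.26) and RAB16C (9.20, SE 0.59) were among the largest rises. Of the single salt markers 4 of 5 rose (4 list-adjusted, adjusted p = 6.01e-05, and 0.111 with an estimated correlation). With limma 9805 genes passed, 5166 higher and 4639 lower, 6621 by at least 2-fold. The 3 salt and 3 control libraries did not overlap in 9404 of them, nor in 43.1% of tested genes. Salt replicate 2 correlated with its sister libraries at 0.94 and 0.924. Without it and the CSR28 control library 10990 genes passed. Between genotypes at 54 h 2061 genes were higher in both (500 by chance), 1912 lower in both (481.9 by chance) and 51 opposite. At 6 h the shared genes were 1458 higher (227.1 by chance) and 1191 lower (194.8 by chance), with 36 opposite. Between times CSR28 roots shared 1584 higher (343 by chance) and 1961 lower (378.4 by chance), with 95 opposite. IR28 roots shared 1380 (331 by chance) and 908 (248.1 by chance), with 188 opposite.

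**Figure D2:**
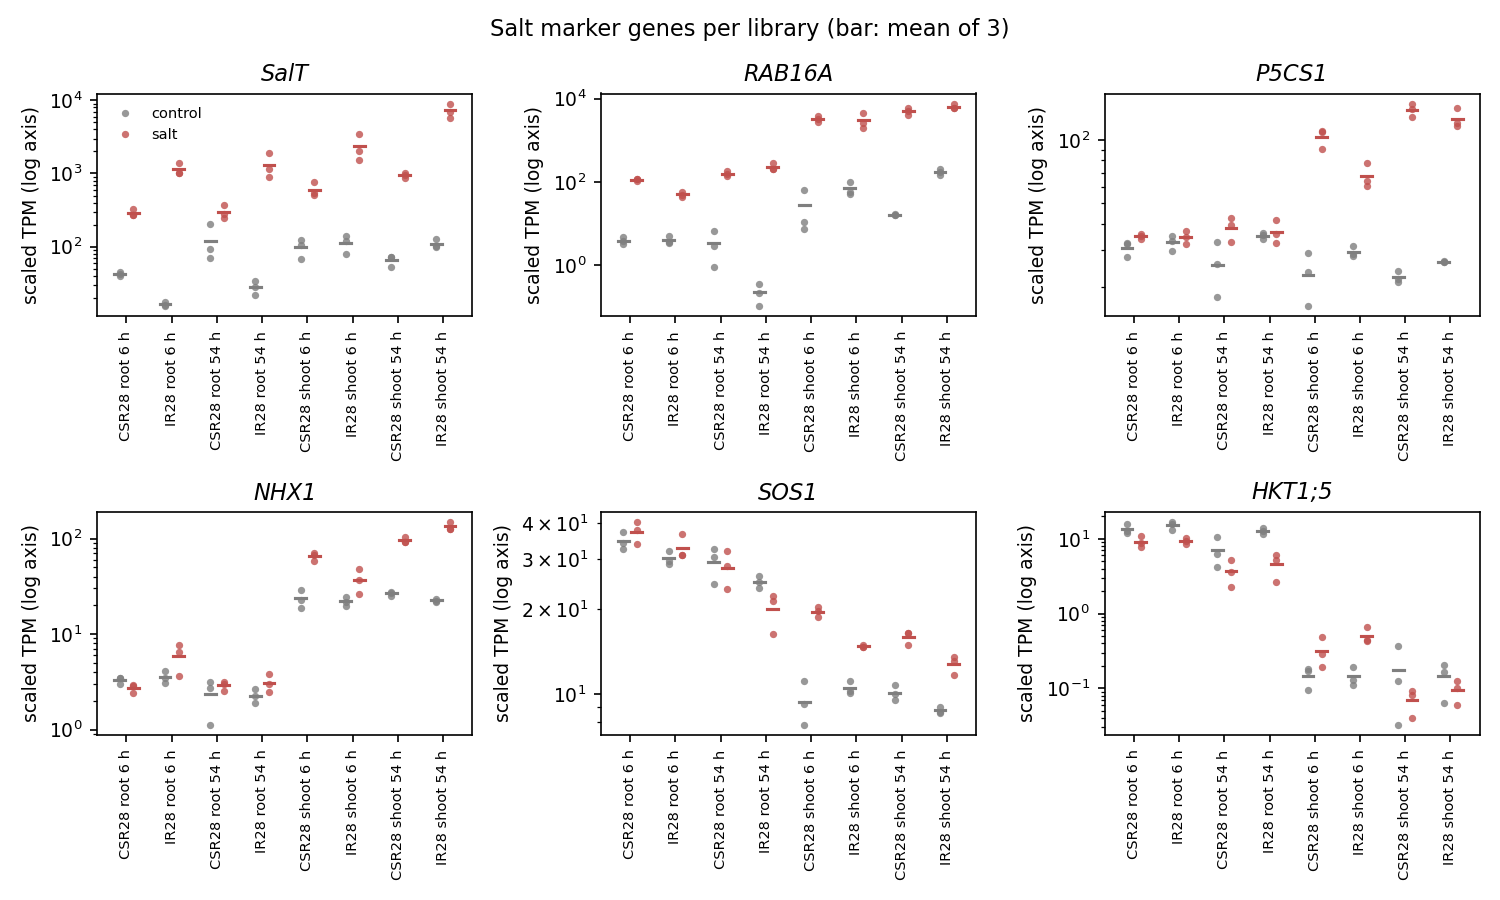
Levels of 6 salt-related genes (scaled TPM, log axis) in the 16 groups, with grey points for control libraries, red points for salt libraries and a bar at the mean of 3. SalT with salt reached 7260 ± 1630 in IR28 shoots at 54 h against 940 ± 65.7 in CSR28 shoots.

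In CSR28 shoots after 6 h of salt, RAB16A stood at 3300 ± 590 against 27.2 ± 31.3 scaled TPM (log2 fold 7.50, SE 0.47, adjusted p = 4.99e-11, n = 3 per group). The vacuolar sodium/proton exchanger gene NHX1 rose to 65.1 ± 6.39 from 23.6 ± 5.25 (log2 fold 1.44, SE 0.16, adjusted p = 1.82e-07) and the plasma membrane exchanger gene SOS1 to 19.5 ± 0.794 from 9.39 ± 1.69 (log2 fold 1.02, SE 0.09, adjusted p = 1.14e-08). P5CS1, the first enzyme of proline synthesis, rose to 103 ± 11.4 from 22.8 ± 6.36 (log2 fold 2.16, SE 0.14, adjusted p = 6.54e-11). SalT stood at 600 ± 135 against 98.9 ± 28.7 (log2 fold 2.57, SE 0.27, adjusted p = 8.27e-08).

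All 9 LEA and dehydrin genes rose in CSR28 shoots at 6 h (9 list-adjusted), RAB16D at 8.46, SE 0.62 and WSI18 at 7.29, SE 0.43 (camera adjusted p = 1.95e-11, and 0.0681 with an estimated correlation). Protein phosphatases rose in 8 of 9 (8 list-adjusted), PP2C68 at 3.93, SE 0.23 (adjusted p = 8.24e-09, and 0.0681 with an estimated correlation). Stress transcription factors gave 17 higher and 1 lower of 23 (17 and 2 list-adjusted), HOX24 at 7.14, SE 0.55, ZFP182 at 5.52, SE 0.40 and SNAC1 at 3.41, SE 0.26 (adjusted p = 2.75e-08, and 0.132 with an estimated correlation). Chlorophyll breakdown genes rose in 5 of 6 (5 list-adjusted), PAO at 2.29, SE 0.12 and NAP at 3.38, SE 0.22 (adjusted p = 1.02e-05, and 0.119 with an estimated correlation). Photosynthesis genes fell in 18 of 19 (18 list-adjusted), LHCB2 at -1.47, SE 0.19 and PORB at -1.62, SE 0.13 (adjusted p = 5.40e-08, and 0.296 with an estimated correlation). Their median of -1.02 was -0.80 without control replicate 1, where the markers lay a median of 0.79 above the sister libraries. Cytosolic ribosomal protein genes gave 2 higher and 111 lower of 121 (2 and 111 list-adjusted), with a median of -1.21 (adjusted p = 1.13e-26, and 0.296 with an estimated correlation). The median was -0.89 without control replicate 1 and -0.78 with length-corrected values. These genes are short (median relative length 0.28), and deviations of that library ran with length at a Spearman correlation of -0.57. Histones gave 2 and 31 of 57 (3 and 33 list-adjusted, adjusted p = 3.65e-07, and 0.296 with an estimated correlation). Sodium and potassium transporters gave 8 higher and 4 lower of 20 (8 and 4 list-adjusted, adjusted p = 0.0915), with SOS2 at 1.41, SE 0.12 and HKT1;4 at -3.08, SE 0.31. Osmolyte genes gave 7 and 4 of 12 (7 and 5 list-adjusted, adjusted p = 0.0671, and 0.0466 without CSR28 shoot 6 h salt replicate 2), P5CS2 at 4.48, SE 0.27.

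The glyoxylate cycle gene for isocitrate lyase, LOC_Os07g34520, rose by 7.86, SE 0.54 in CSR28 shoots at 6 h, and NCED4 by 6.40, SE 0.52. The dioxygenase LOC_Os08g15149 (-7.75, SE 0.38) and the terpene synthase LOC_Os08g07080 (-6.37, SE 0.32) fell. With limma 14905 genes passed, 6806 higher and 8099 lower, 8439 by at least 2-fold. For 13180 of these genes, and for 44.6% of tested genes, salt and control libraries did not overlap. Control replicate 1 of this group correlated with its sister libraries at 0.956 and 0.937. Without it 13565 genes passed. Fitted on only these groups 8286 passed, and LHCB2 did not (adjusted p = 0.134).

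At 54 h CSR28 shoots showed the homeobox gene HOX24 at 348 ± 58.6 against 0.246 ± 0.164 scaled TPM (log2 fold 10.55, SE 0.55, adjusted p = 7.02e-13, n = 3 per group). RAB16A reached 5123 ± 997 from 16.2 ± 0.768 (log2 fold 8.31, SE 0.47, adjusted p = 2.32e-12) and NHX1 96.3 ± 7 from 26.67 ± 1.24 (log2 fold 1.88, SE 0.16, adjusted p = 1.37e-09). Rubisco activase RCA, needed for carbon fixation, fell from 12670 ± 374 to 1662 ± 292 (log2 fold -2.91, SE 0.18, adjusted p = 8.02e-12), and the chlorophyll synthesis gene CHLH from 657 ± 15.2 to 78.3 ± 8.07 (log2 fold -3.04, SE 0.13, adjusted p = 5.11e-14).

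All 19 photosynthesis genes fell at 54 h (19 list-adjusted), with a median of -2.34 and LHCB6 at -3.02, SE 0.15 (camera adjusted p = 1.72e-13, and 0.129 with an estimated correlation). All 6 chlorophyll breakdown genes rose (6 list-adjusted), PAO at 2.82, SE 0.12 (adjusted p = 2.87e-07, and 0.0539 with an estimated correlation). Dehydrin and LEA genes rose in 9 of 9 (9 list-adjusted, median 8.31), WSI18 at 8.60, SE 0.43 (adjusted p = 1.22e-11, and 0.0529 with an estimated correlation). Protein phosphatases rose in 8 of 9 (8 list-adjusted), PP2C53 at 6.50, SE 0.37 (adjusted p = 9.53e-10, and 0.0529 with an estimated correlation). Heat shock genes rose in 5 of 7 (5 list-adjusted, adjusted p = 0.00206, and 0.0529 with an estimated correlation). Cellulose synthases fell in 6 of 6 (6 list-adjusted), CESA4 at -2.72, SE 0.20 (adjusted p = 2.36e-05, and 0.157 with an estimated correlation). Antioxidant genes were split, 4 higher and 4 lower of 10 (4 and 4 list-adjusted, adjusted p = 0.482), with the catalases CATB at 2.17, SE 0.11, CATA at -1.56, SE 0.17 and CATC at -1.38, SE 0.15. Aquaporins gave 6 higher and 3 lower of 14 (6 and 4 list-adjusted), with a median of -0.17 and a test direction of higher (adjusted p = 0.739).

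NAC10 (7.80, SE 0.46), NCED4 (6.98, SE 0.52) and the membrane protein gene LOC_Os05g31670 (AWPM-19, 9.69, SE 0.64) were further large rises. HKT1;3 (-2.07, SE 0.16), the clock gene LHY (-1.82, SE 0.11), the plastid glutamine synthetase GS2 (-1.65, SE 0.13) and the P450 gene LOC_Os09g10340 (-6.13, SE 0.19) fell. With limma 14429 genes passed, 6145 higher and 8284 lower, 8913 by at least 2-fold. Groups lay fully apart in 14074 of them and in 54% of tested genes. Without the 6 h control library that stood apart 15869 genes passed.

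IR28 shoots at 6 h had SalT at 2357 ± 1020 against 113 ± 30.4 scaled TPM (log2 fold 4.31, SE 0.27, adjusted p = 2.43e-10, n = 3 per group) and RAB16A at 3015 ± 1280 against 69.8 ± 26.4 (log2 fold 5.39, SE 0.47, adjusted p = 2.20e-08). P5CS1 (1.17, SE 0.14), NHX1 (0.71, SE 0.16) and SOS1 (0.47, SE 0.09) rose. A P450 gene, LOC_Os09g10340, fell from 618 ± 65.4 to 19.4 ± 4.36 (log2 fold -5.03, SE 0.19, adjusted p = 1.19e-13).

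Heat shock genes rose in 5 of 7 in IR28 shoots at 6 h (6 list-adjusted), HSP101 at 1.66, SE 0.13 (camera adjusted p = 4.18e-05, and 0.0182 with an estimated correlation). Dehydrin and LEA genes rose in 9 of 9 (9 list-adjusted), RAB16D at 7.68, SE 0.62 (adjusted p = 7.24e-16, and 0.0182 with an estimated correlation). The wider set of genes described as LEA or dehydrin gave 21 higher and 1 lower of 31 (21 and 1 list-adjusted, adjusted p = 2.20e-17, and 0.0182 with an estimated correlation). Protein phosphatases rose in 8 of 9 (8 list-adjusted), PP2C53 at 4.48, SE 0.37 (adjusted p = 3.67e-09, and 0.0507 with an estimated correlation). Stress transcription factors gave 16 higher and 1 lower of 23 (17 and 1 list-adjusted), SNAC1 at 3.12, SE 0.26 (adjusted p = 2.53e-10, and 0.0700 with an estimated correlation). Chlorophyll breakdown genes rose in 5 of 6 (5 list-adjusted), PAO at 1.76, SE 0.12 (adjusted p = 2.11e-07, and 0.0507 with an estimated correlation). Photosynthesis genes fell in 16 of 19 (18 list-adjusted), RCA at -0.97, SE 0.18 (adjusted p = 1.14e-08, and 0.346 with an estimated correlation). Ribosomal protein genes gave 3 higher and 58 lower of 121, and 94 lower without CSR28 control replicate 1 (3 and 79 list-adjusted), with a median of -0.47 (adjusted p = 7.66e-12, and 0.626 with an estimated correlation).

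NCED4 (6.51, SE 0.52) and the lipid transfer gene LOC_Os04g33920 (7.77, SE 0.53) rose in IR28 shoots at 6 h. NAAT1 (-1.98, SE 0.15), an enzyme of iron chelator synthesis, PIP2;5 (-3.46, SE 0.38) and LHY (-1.39, SE 0.11) fell. With limma 8187 genes passed, 3614 higher and 4573 lower, 3621 by at least 2-fold. The 3 salt and 3 control libraries did not overlap in 7966 of them, nor in 40.9% of tested genes. Without the library that stood apart in CSR28 9985 genes passed. Fitted on only these groups NHX1 did not pass (adjusted p = 0.102).

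In IR28 shoots at 54 h SalT reached 7260 ± 1630 scaled TPM from 110 ± 15.5 (log2 fold 6.05, SE 0.27, adjusted p = 6.98e-14, n = 3 per group) and RAB16A 6443 ± 1010 from 177 ± 30.5 (log2 fold 5.20, SE 0.47, adjusted p = 4.09e-09). NHX1 rose to 134 ± 12.7 from 22.5 ± 0.727 (log2 fold 2.58, SE 0.16, adjusted p = 8.48e-12), and RCA fell to 1171 ± 25.5 from 8666 ± 755 (log2 fold -2.87, SE 0.18, adjusted p = 9.91e-12). The terpene synthase LOC_Os08g04500 fell to 8.29 ± 2.51 from 764 ± 41.2 (log2 fold -6.59, SE 0.20, adjusted p = 5.79e-16).

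Sodium and potassium transporters gave 11 higher and 3 lower of 20 in IR28 shoots at 54 h (11 and 3 list-adjusted), HKT1;1 at 2.15, SE 0.15 and HKT1;3 at -2.50, SE 0.16 (camera adjusted p = 0.00112, and 0.178 with an estimated correlation). All 19 photosynthesis genes fell (19 list-adjusted), LHCB6 at -2.46, SE 0.15 and CHLH at -2.58, SE 0.13 (adjusted p = 1.55e-11, and 0.178 with an estimated correlation). All 6 chlorophyll breakdown genes rose (6 list-adjusted), PAO at 2.91, SE 0.12, SGR at 2.54, SE 0.24 and NYC3 at 2.40, SE 0.16 (adjusted p = 4.27e-07, and 0.0830 with an estimated correlation). All 9 LEA and dehydrin genes rose (9 list-adjusted), WSI18 at 7.27, SE 0.43 (adjusted p = 2.10e-09, and 0.0830 with an estimated correlation). Protein phosphatases rose in 8 of 9 (8 list-adjusted), PP2C53 at 5.84, SE 0.37 (adjusted p = 4.16e-08, and 0.0830 with an estimated correlation). Ribosomal protein genes gave 3 higher and 107 lower of 121 (3 and 108 list-adjusted, adjusted p = 1.01e-14, and 0.439 with an estimated correlation). Small heat shock proteins had a median of -0.20, a mean of 0.37 and a test direction of higher (adjusted p = 0.874), with 7 higher and 12 lower of 28 (8 and 12 list-adjusted). WRKY factors gave 33 and 30 of 103 (33 and 31 list-adjusted), with a median of -0.18 and a test direction of higher (adjusted p = 0.572).

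HOX24 (7.32, SE 0.55), NCED4 (7.10, SE 0.52), P5CS1 (2.27, SE 0.14) and CATB (2.34, SE 0.11) rose, and NiR (-1.58, SE 0.15), CESA4 (-2.75, SE 0.20) and the MYB factor LOC_Os01g47370 (-7.29, SE 0.55) fell. With limma 15176 genes passed, 6517 higher and 8659 lower, 9681 by at least 2-fold. For 14776 of these genes, and for 55.3% of tested genes, salt and control libraries did not overlap. Without the library that stood apart 16440 genes passed. Between genotypes at 54 h shoots shared 4876 higher genes (1191.7 by chance) and 6716 lower ones (2134.5 by chance), with 103 opposite. At 6 h they shared 2849 (731.9 by chance) and 3625 (1102.1 by chance), with 64 opposite. Between times CSR28 shoots shared 3890 (1244.5 by chance) and 5388 (1996.4 by chance), with 473 opposite. IR28 shoots shared 2866 (700.8 by chance) and 3563 (1178.3 by chance), with 200 opposite.

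**Figure D3:**
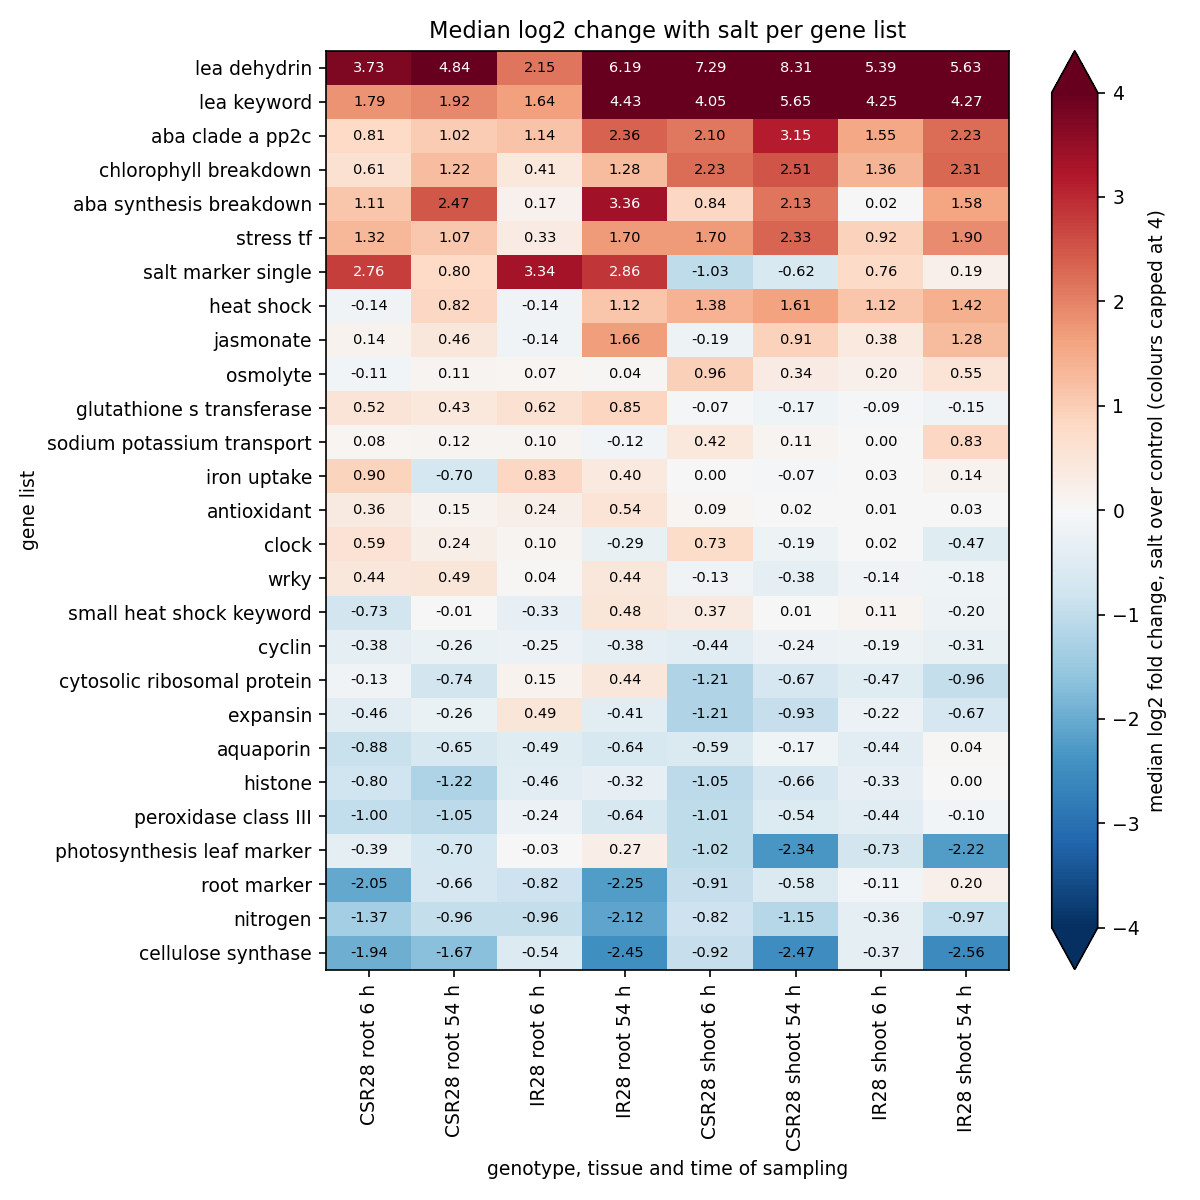
Median log2 fold with salt of 27 gene lists in the 8 genotype, tissue and time groups, with red for higher, blue for lower and colours capped at 4. LEA and dehydrin genes had the largest medians in shoots, 8.31 in CSR28 and 5.63 in IR28 at 54 h, and cellulose synthases medians of -2.47 and -2.56.

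The genotypes differed in how SalT responded to salt. In roots its response was smaller in CSR28 at 6 h (difference of log2 folds -3.31, SE 0.45, adjusted p = 8.22e-04, n = 3 per group) and at 54 h (-4.16, SE 0.45, adjusted p = 5.25e-05), and the same held in shoots at 6 h (-1.74, SE 0.38, adjusted p = 0.0104) and 54 h (-2.16, SE 0.38, adjusted p = 0.00194). The cold and drought response factor DREB1B went from 1.04 ± 0.171 to 18.3 ± 4.58 scaled TPM with salt in CSR28 roots at 6 h and from 3.46 ± 1.46 to 0.703 ± 0.356 in IR28 roots (difference 6.33, SE 0.98, adjusted p = 0.00230). DREB1A followed with 2.48 ± 0.449 to 26.4 ± 2.64 in CSR28 and 7.85 ± 1.67 to 4.50 ± 1.20 in IR28 (difference 4.22, SE 0.64, adjusted p = 0.00211), and DREB1C with a difference of 4.90, SE 0.71. The secondary wall genes CESA4 (-1.39, SE 0.24) and CESA7 (-1.53, SE 0.28), TIP2;1 (-2.04, SE 0.34), a BURP gene LOC_Os05g12640 (-4.24, SE 0.44) and the sugar transporter family gene LOC_Os05g12320 (-3.89, SE 0.53) were lower in the CSR28 response. By contrast WSI18 (2.10, SE 0.43), the kinase LOC_Os11g46880 (4.48, SE 0.71) and the secreted protein LOC_Os07g03580 (4.16, SE 0.64) were higher.

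By groups, cellulose synthases fell further in CSR28 roots at 6 h, with 3 of 6 passing (5 list-adjusted) and a median difference of -1.39 (camera adjusted p = 9.43e-08, and 0.0695 with an estimated correlation). Expansins gave 0 higher and 9 lower of 55 (1 and 21 list-adjusted, adjusted p = 1.40e-13, and 0.0695 with an estimated correlation). The difference test of limma passed 663 genes at 6 h, 292 higher and 371 lower, 2282 without the libraries that stood apart at 54 h and 2186 fitted on only these 4 groups. With 1 library left out it ran from 251 to 741.

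In roots at 54 h RAB16A went from 3.48 ± 2.88 to 159 ± 25.6 in CSR28 and from 0.226 ± 0.126 to 231 ± 53.0 in IR28 (difference -3.98, SE 0.64, adjusted p = 0.00291). Among the protein phosphatases PP2C68 (-2.90, SE 0.36), PP2C08 (-1.91, SE 0.31) and PP2C09 (-1.61, SE 0.29) differed the same way, and so did HOX24 (-3.68, SE 0.56) and JAZ12 (-2.37, SE 0.47). The jacalin gene LOC_Os01g25280 (5.20, SE 0.83) and the defensin gene LOC_Os11g47269 (4.31, SE 0.78) had positive differences, and the dehydrogenase LOC_Os08g37130 (-4.39, SE 0.87) a negative one. Protein phosphatases passed as lower in 5 of 9 (7 list-adjusted, median -1.61, adjusted p = 1.13e-06, and 0.109 with an estimated correlation). Dehydrin and LEA genes passed as lower in 3 of 9 (7 list-adjusted, median -1.59, adjusted p = 1.44e-06, and 0.109 with an estimated correlation). In all 712 genes passed with limma, 205 higher and 507 lower, and 382 without the libraries that stood apart, 305 of them among the 712. Fitted on only these 4 groups 67 genes passed. Of the genes named here PP2C68 kept its call. Lost were those of RAB16A (adjusted p = 0.103), PP2C08 (0.0863), PP2C09 (0.118), HOX24 (0.0658), JAZ12 (0.155), LOC_Os01g25280 (0.0581), LOC_Os11g47269 (0.101) and LOC_Os08g37130 (0.0638). The count hung on single libraries, running from 284 without CSR28 salt replicate 3 to 7301 without CSR28 control replicate 3.

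For shoots at 6 h P5CS1 (0.99, SE 0.20), SOS1 (0.55, SE 0.13), SOS2 (0.94, SE 0.17), the phosphatase PP2C30 (1.55, SE 0.31), the chlorophyll breakdown gene NYC1 (1.07, SE 0.22) and the clock gene PRR95 (1.01, SE 0.23) had higher responses in CSR28. HKT1;4 (-2.05, SE 0.44), NAAT1 (-1.17, SE 0.21) and the dioxygenase LOC_Os08g15149 (-5.15, SE 0.53) had lower ones. Sodium and potassium transport genes gave 4 higher and 1 lower of 20 (8 and 1 list-adjusted, adjusted p = 0.00780, and 0.310 with an estimated correlation). Protein phosphatases gave 5 higher of 9 (7 list-adjusted, adjusted p = 1.41e-04, and 0.310 with an estimated correlation). Ribosomal protein genes gave 0 higher and 34 lower of 121 (1 and 95 list-adjusted, adjusted p = 1.04e-24, and 0.310 with an estimated correlation). Histones gave 0 and 15 of 57 (0 and 24 list-adjusted, adjusted p = 4.53e-09, and 0.310 with an estimated correlation). The ribosomal count was 22 without CSR28 control replicate 1 and 42 with length-corrected values, with medians of -0.39 and -0.40 instead of -0.71. The histone count was not worked out in these settings. With limma 2419 genes passed, 1200 higher and 1219 lower, and 1894 without CSR28 control replicate 1. Fitted on only these 4 groups 335 passed. P5CS1 (adjusted p = 0.0771), SOS1 (0.0904), SOS2 (0.0561), PP2C30 (0.0831), NYC1 (0.0842), PRR95 (0.103), HKT1;4 (0.0822) and SalT (0.0963) then lost their call. With 1 library left out the count ran from 943 without IR28 salt replicate 3 to 6267 without CSR28 control replicate 3.

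At 54 h 824 genes passed in shoots with limma, 392 higher and 432 lower. The count was 1371 without the 6 h control library that stood apart, 1494 fitted on only the groups compared and 1512 with scaled TPM. RAB16A rose more in CSR28 shoots (3.11, SE 0.67, adjusted p = 0.0104), where its control level was 16.2 ± 0.768 against 177 ± 30.5 in IR28. DREB1A (3.05, SE 0.64), DREB1B (3.68, SE 0.69), HAK16 (-1.29, SE 0.17), HKT1;4 (-2.05, SE 0.44) and the silicon channel gene NIP2;1 (-1.54, SE 0.31) also differed. The terpene synthase LOC_Os08g07080 (5.87, SE 0.45) and the methyltransferase LOC_Os12g10170 (5.05, SE 0.89) had higher responses in CSR28, and the BURP gene LOC_Os05g13490 (-9.42, SE 0.76) a lower one. LEA and dehydrin genes gave 2 higher of 9 (5 list-adjusted, median 1.43, camera adjusted p = 5.15e-05, and 0.686 with an estimated correlation).

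Responses at 54 h were compared with those at 6 h. In IR28 roots RAB16B (6.87, SE 0.78, adjusted p = 1.01e-05, n = 3 per group) and RAB16C (6.41, SE 0.83, adjusted p = 4.52e-05) had higher responses at 54 h, and the peroxidase LOC_Os07g31610 (-7.78, SE 0.84, adjusted p = 6.04e-06) a lower one. All 9 LEA and dehydrin genes had higher responses (9 list-adjusted, median 3.71, camera adjusted p = 8.72e-16, and 0.00385 with an estimated correlation). So did 7 of 9 protein phosphatases (8 list-adjusted, adjusted p = 9.44e-09, and 0.0164 with an estimated correlation). For 5 of 7 abscisic acid synthesis and breakdown genes (5 list-adjusted, adjusted p = 1.49e-05, and 0.0199 with an estimated correlation) and for 11 of 23 stress transcription factors (16 higher and 1 lower list-adjusted, adjusted p = 7.59e-09, and 0.00539 with an estimated correlation) the same was seen. Cellulose synthases fell further in 5 of 6 (6 list-adjusted, adjusted p = 1.27e-07, and 0.0340 with an estimated correlation). With limma 3029 genes passed in IR28 roots, 1706 higher and 1323 lower, and 4823 without the libraries that stood apart. In CSR28 roots 1201 passed, 636 higher and 565 lower, 2209 without those libraries and 603 fitted on only the groups compared, with iron uptake genes lower in 3 of 7 (5 list-adjusted, median -1.65, adjusted p = 9.31e-08, and 0.0940 with an estimated correlation). The response of the cinnamoyl-CoA reductase LOC_Os08g17500 was higher at 54 h in CSR28 roots (7.93, SE 0.99) and that of the secreted protein LOC_Os07g03580 lower (-7.61, SE 0.64).

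In shoots photosynthesis genes had lower responses at 54 h than at 6 h in 14 of 19 genes in CSR28 (16 list-adjusted, adjusted p = 3.75e-10, and 0.565 with an estimated correlation) and in 14 of 19 in IR28 (16 list-adjusted, adjusted p = 1.72e-10, and 0.341 with an estimated correlation). All 6 cellulose synthases did so in CSR28 (6 list-adjusted, adjusted p = 3.00e-05, and 0.565 with an estimated correlation). So did all 6 in IR28 (6 list-adjusted, adjusted p = 1.15e-06, and 0.341 with an estimated correlation). Clock genes had lower responses at 54 h in 7 of 8 in CSR28 shoots (7 list-adjusted, adjusted p = 1.49e-05, and 0.565 with an estimated correlation). Sodium and potassium transporters had higher ones in 10 of 20 in IR28 shoots (12 higher and 3 lower list-adjusted, adjusted p = 3.31e-05, and 0.341 with an estimated correlation). The protease inhibitor gene LOC_Os12g36220 (7.55, SE 1.10) in CSR28 and the lipid transfer protein gene LOC_Os08g01710 (6.24, SE 1.16) in IR28 had higher responses at 54 h. With limma 6270 genes passed in CSR28 shoots, 2711 higher and 3559 lower (6178 without the library that stood apart, 3914 fitted on only the groups compared), and 6629 in IR28 shoots, 2722 higher and 3907 lower (8426 without it).

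Without salt the genotypes also differed. Both were quantified against the same transcript models, so differences in mapping can add to the values and counts of this comparison. The BURP gene LOC_Os05g12410 stood at 894 ± 36.1 against 0.561 ± 0.155 scaled TPM in CSR28 against IR28 roots at 6 h and at 712 ± 91.0 against 3.10 ± 2.30 in shoots at 54 h. A glutathione S-transferase gene, LOC_Os10g38630, showed the reverse (log2 difference -10.51, SE 0.58, adjusted p = 1.93e-11 in roots at 6 h). Photosynthesis genes were higher in CSR28 control roots, 18 of 19 at 6 h (18 list-adjusted, median 1.47, camera adjusted p = 6.35e-20, and 0.385 with an estimated correlation) and 18 of 19 at 54 h (19 list-adjusted, median 1.39, adjusted p = 8.98e-14, and 0.359 with an estimated correlation). Iron uptake genes were higher in 5 of 7 in CSR28 roots at 54 h (5 list-adjusted, adjusted p = 9.18e-06, and 0.289 with an estimated correlation). In shoots at 6 h ribosomal protein genes were higher in CSR28 in 92 and lower in 3 of 121, with a median of 0.64 (103 and 3 list-adjusted, adjusted p = 1.48e-20, and 0.644 with an estimated correlation). Without CSR28 control replicate 1, 53 were higher and the median was 0.32. LEA and dehydrin genes were lower in 5 of 9 in CSR28 shoots at 54 h (8 list-adjusted, median -2.13, adjusted p = 3.88e-05, and 0.342 with an estimated correlation).

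With limma 4067 genes differed between control roots at 6 h, 2167 higher in CSR28 and 1900 lower, and 5839 at 54 h, 3386 higher and 2453 lower. In control shoots 8129 differed at 6 h, 3691 higher and 4438 lower, and 5218 at 54 h, 2337 higher and 2881 lower. Groups lay fully apart in 32.5%, 30.4%, 30.5% and 34.3% of tested genes in that order. Without the libraries that stood apart the counts were 6212, 5072, 6611 and 6594. Fitted on only the groups compared they were 2322 in roots at 54 h and 3002 in shoots at 6 h. Leaving out CSR28 control replicate 3 raised the root count at 54 h to 11576.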

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

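Except for the photosynthesis genes of control roots and the split counts of salt and control comparisons, the results below were picked out because the test of the difference itself passed, that is, the limma test of how the salt response differed between genotypes or between times at adjusted p < 0.05, with 3 libraries per group. Genes are those with the largest differences under the naming rule. Lists are those with a camera adjusted p < 0.05 and at least 35% of members passing adjusted over the list alone. That share was set after a first rule of 25% over all genes had been seen, and the change brought in the expansin list of roots at 6 h. The tests of library, tissue, scaling and length effects, the breakdown of splits by pairs, and the use of a spread term to judge them were also chosen after seeing results. Of the predictions for these tests 4 were written before their results and 22 after.

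The genotype difference passed in 663 genes in roots at 6 h, 712 in roots at 54 h, 2419 in shoots at 6 h and 824 in shoots at 54 h. These counts rest on a spread shared over all libraries of a tissue. Fits on only the groups compared, given above, put them in another order, so their sizes should not be ranked. The time difference passed in 1201 genes in CSR28 roots, 3029 in IR28 roots, 6270 in CSR28 shoots and 6629 in IR28 shoots.

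Genes whose response differed between genotypes in roots at 6 h were DREB1B (6.33), LOC_Os11g46880 (4.48), DREB1A (4.22) and LOC_Os07g03580 (4.16) with positive differences (CSR28 less IR28). Negative ones were those of the lipid transfer genes LOC_Os10g36090 (-5.86) and LOC_Os10g40460 (-3.55), LOC_Os05g12640 (-4.24) and LOC_Os05g12320 (-3.89). In roots at 54 h the positive ones were the jacalin LOC_Os01g25280 (5.20), the defensin LOC_Os11g47269 (4.31), the amidotransferase LOC_Os02g08270 (4.13), the kinase LOC_Os05g14220 (3.88) and the cupin LOC_Os08g13440 (3.22). Negative ones were LOC_Os08g37130 (-4.39), the F-box gene LOC_Os09g17530 (-4.34), the universal stress protein LOC_Os03g53900 (-4.30), SalT (-4.16) and the aldo/keto reductase LOC_Os10g02480 (-4). When 1 library was left out, LOC_Os10g36090 lost its call in roots at 6 h (adjusted p = 0.0508 without CSR28 control replicate 1 and 0.0522 without CSR28 salt replicate 2), and LOC_Os10g40460 lost it for 9 of the 12 libraries, up to 0.114 without CSR28 salt replicate 2. At 54 h LOC_Os05g14220 lost it for 9 libraries, up to 0.135 without CSR28 salt replicate 3, and LOC_Os03g53900 for IR28 salt replicate 2 (0.0525). Fitted on only the groups compared LOC_Os01g25280 (0.0581), LOC_Os11g47269 (0.101), LOC_Os05g14220 (0.278), LOC_Os08g37130 (0.0638), LOC_Os09g17530 (0.0893) and LOC_Os03g53900 (0.122) lost theirs at 54 h.

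In shoots at 6 h the positive genes were the methyltransferases LOC_Os11g19840 (4.34) and LOC_Os12g10170 (3.24), LOC_Os01g12820 (4.17), LOC_Os09g08490 (3.74) and LOC_Os12g36630 (3.31). The negative ones were the dioxygenase LOC_Os08g15149 (-5.15), the histone H3 gene LOC_Os06g06510 (-4.87), the inhibitor LOC_Os12g36220 (-4.64) and the terpene synthase LOC_Os04g52210 (-4.62). In shoots at 54 h LOC_Os08g07080 (5.87), LOC_Os12g10170 (5.05) and the LEA gene LOC_Os04g49980 (4.39) were positive, and LOC_Os05g13490 (-9.42), the transporter LOC_Os01g36720 (-3.67), the P450 LOC_Os01g36350 (-3.59), the receptor kinase LOC_Os06g05050 (-3.52) and the ASR gene LOC_Os01g72900 (-3.52) negative. At 6 h LOC_Os12g10170 lost its call for 7 libraries, up to 0.0743 without IR28 shoot 6 h control replicate 1, LOC_Os09g08490 for 8, up to 0.0774 without IR28 control replicate 2, and LOC_Os06g06510 for 5, up to 0.0963 without CSR28 salt replicate 3. Fitted on only the groups compared these lost it as well (0.0743, 0.126 and 0.183), as did LOC_Os12g36220 (0.0798), and at 54 h LOC_Os01g36720 (0.063).

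Between times, taken as the response at 54 h less that at 6 h, differences in CSR28 roots were positive for LOC_Os08g17500 (7.93), the ERF factor LOC_Os11g06770 (6.21) and the amylase LOC_Os08g36910 (5.83), and negative for LOC_Os07g03580 (-7.61), the transporter LOC_Os05g31730 (-7.54) and the actin LOC_Os12g44350 (-6.82). In IR28 roots they were positive for RAB16B (6.87) and RAB16C (6.41) and negative for LOC_Os07g35860 (-8.14), LOC_Os07g31610 (-7.78) and LOC_Os04g46820 (-7.78). In CSR28 shoots the inhibitors LOC_Os12g36220 (7.55) and LOC_Os12g36210 (7.50) were positive, and LOC_Os03g48750 (-5.14), LOC_Os01g36720 (-4.85) and LOC_Os03g32470 (-4.83) negative. In IR28 shoots LOC_Os08g01710 (6.24), LOC_Os01g06560 (4.70) and LOC_Os12g36240 (4.58) were positive, and LOC_Os08g07080 (-6.61), LOC_Os01g47370 (-5.43) and LOC_Os03g32470 (-4.80) negative.

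For lists, brackets give the members passing over all genes in the direction of the median. The median difference between genotypes in roots at 6 h was -1.39 (3 of 6) for cellulose synthases and -1.31 (9 of 55) for expansins. In roots at 54 h it was -1.61 (5 of 9) for protein phosphatases, -1.59 (3 of 9) for LEA and dehydrin genes, -1.67 (5 of 29) for the wider LEA set, -0.89 (3 of 19) for photosynthesis, -1.95 (1 of 5) for the single salt markers and -1.18 (0 of 121) for ribosomal proteins. Adjusted over the list alone 16, 17, 5 and 107 passed for the last 4. For the ribosomal list the median was -0.63 without CSR28 root 54 h control replicate 1 and -0.34 without the libraries that stood apart. Without that replicate the same list lost its call for genotype in control roots at 54 h (adjusted p = 0.401) and for time in CSR28 roots (0.454), and without salt replicate 2 for salt in IR28 roots at 54 h (0.360). In shoots at 6 h the median difference was 0.70 (1 of 7) for abscisic acid synthesis and breakdown, 0.78 (5 of 9) for phosphatases, 1.49 (1 of 9) for LEA and dehydrin genes, 0.40 (4 of 20) for sodium and potassium transport, 0.54 (3 of 12) for osmolyte genes, 0.60 (2 of 6) for chlorophyll breakdown, 0.60 (5 of 8) for the clock, -1.74 (1 of 5) for salt markers, -0.71 (34 of 121) for ribosomal proteins and -1.13 (15 of 57) for histones. In shoots at 54 h it was 1.43 (2 of 9) for LEA and dehydrin genes. None of these passed with an estimated correlation.

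The median difference between times in CSR28 roots was 0.67 (1 of 7) for abscisic acid synthesis and breakdown, 1.18 (1 of 9) for LEA and dehydrin genes, -1.65 (3 of 7) for iron uptake, -0.23 (3 of 8) for the clock and -1.35 (2 of 5) for salt markers. In IR28 roots it was 1.99 (5 of 7), 1.5 (7 of 9), 3.71 (9 of 9), 1.07 (11 of 23) and 2.2 (14 of 29) for abscisic acid genes, phosphatases, LEA and dehydrin genes, stress factors and the wider LEA set. It was 0.85 (5 of 10) for jasmonate, -1.18 (2 of 11) for nitrogen, -1.83 (4 of 7) for iron, -1.82 (5 of 6) for cellulose synthases and -1.05 (22 of 55) for expansins. In CSR28 shoots it was 0.51 (6 of 14) for aquaporins, -1.61 (6 of 6) for cellulose synthases, -0.94 (7 of 8) for the clock and -1.08 (14 of 19) for photosynthesis. In IR28 shoots it was 0.58 (3 of 7) for abscisic acid genes, 1.15 (4 of 9) for phosphatases, 0.62 (10 of 20) for sodium and potassium transport, 0.48 (6 of 14) for aquaporins, -2.04 (6 of 6) for cellulose synthases, 1.05 (5 of 6) for chlorophyll breakdown and -1.36 (14 of 19) for photosynthesis. With an estimated correlation only IR28 root lists passed, namely abscisic acid genes, phosphatases, LEA and dehydrin genes, stress factors, the wider LEA set and cellulose synthases. Calls that some single library carried were the clock list of CSR28 roots (0.212 without control replicate 3 of 54 h), the salt markers there (0.274 without control replicate 1 of 54 h), the nitrogen list of IR28 roots (0.117 without salt replicate 2 of 54 h) and the aquaporin list of IR28 shoots (0.118 without salt replicate 2 of 6 h).

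Photosynthesis genes were higher in CSR28 than in IR28 control roots at 6 h. Shoot tissue in the root samples would lift all markers by one share of their shoot level, but among the 5 most abundant markers the lowest stood at 0.183% of its shoot level while the list median was 4.21%, which argues against it as the whole cause. The list median of 1.47 lay 1.45 (SE 0.20) above that of 21139 other genes. Size factors hold the latter small (0.02), so this cannot test scaling. The difference between the genotypes itself was tested above, but no further cause of it was tested, and the cause stays open.

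Over 18 LEA, dehydrin and phosphatase genes the median difference of the response (CSR28 less IR28) in roots at 54 h was -1.60. Of these 8 passed, and neither list passed with an estimated correlation (0.109). Without the control library that stands apart the median was -1.20 (SE 0.26), and without the length trend -1.22 (SE 0.29). Both argue against these as the whole cause (7 genes passed in each), but IR28 salt replicate 2 stayed in. Most calls were lost fitting only these groups. CSR28 controls were higher (median 0.89, and 0.57 and 0.62 here), so part of the difference lay in the control library's group. A genotype difference stays open.

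Over 121 ribosomal protein genes the median difference of the response in shoots at 6 h was -0.71. Of these 34 passed, and the list did not with an estimated correlation (0.310). Without the control library that stands apart it was -0.39 (SE 0.12), and with length-corrected values -0.40 (SE 0.12), with 22 and 42 genes passing. These tests left the cause undecided, and part of the difference may come from that library.

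For the 12 comparisons of a pair of groups the 6 libraries can be split in only 10 ways, too few for a share under 0.05. The true split had the most genes each time, as 1 of 10. The other splits mix the groups compared, so a true difference widens their spread and lowers their counts by construction. For salt in roots the true and highest other counts were 7187 and 1, 6668 and 1104 (CSR28), 3906 and 2, 9805 and 5 (IR28), at 6 h and 54 h. In shoots they were 14905 and 13, 14429 and 2 (CSR28), 8187 and 4, 15176 and 3 (IR28). For control plants they were 4067 and 1, 5839 and 3 in roots, 8129 and 19, 5218 and 2 in shoots. The 1104 of CSR28 roots at 54 h came from a split that left replicates of the same number on one side, and splits that parted every such pair had 0.

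For the differences of responses 100 of 200 splits were drawn. As many genes as the true split were called in 10 of them for genotypes in roots at 6 h (663, highest other 8597) and in 9 at 54 h (712, highest other 11101). It was 9 in shoots at 6 h (2419, highest other 11515) and 12 at 54 h (824, highest other 17870). For times it was 10 in CSR28 roots (1201, highest other 6113), 8 in IR28 roots (3029, highest other 9256), 12 in CSR28 shoots (6270, highest other 12453) and 11 in IR28 shoots (6629, highest other 15761). From the share alone chance cannot be excluded. Every other split with as many left the true split of 1 pair of groups whole, so that a salt response itself entered the difference. Of the splits mixing both pairs the highest counts were 1 and 8 in roots and 3 and 1 in shoots between genotypes, and 4, 4, 5 and 8 between times. Such mixing puts the salt response into the spread within groups, which lowers these counts by construction. Neither kind of split stands for equal salt responses on both sides, so the splits cannot decide on chance.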

How the results depend on the processing

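The design and most alternatives were set before the data were examined. Weights per library and the runs without the libraries that stood apart were chosen after seeing the data. Median-of-ratios scaling, a pseudocount of 1, no filter and transcript-level tests moved 0 of the 20 counts by more than 1.5 times, and scaling moved the median over all genes by at most 0.047. A replicate block, shared by all groups of a tissue, moved 0 of 20 counts and cannot test pairing in 1 comparison. Results of named genes, called or not, stayed on their side of the threshold in 1016 cases with median-of-ratios scaling, 1027 with a pseudocount of 1 and 997 with scaled TPM. Fits on only the groups compared kept 868 and made 132 weaker, and leaving out 1 library kept 7620 and made 488 weaker. For lists a correlation estimated from the data was the harder test: 308 results stayed the same and 232 were weaker. Root libraries as low as 6.30 M reads may miss small changes and weak genes. The cause of a moved value below was not tested unless stated.

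A filter of 1 per M in 12 libraries gave 2708 genes for genotype in control roots at 6 h, with fewer genes tested. Scaled TPM gave 1008 and 1148 for the genotype difference of the response in roots at 6 h and 54 h and 1512 in shoots at 54 h. Without the variance trend the shoot count at 6 h was 1382. Fits on only the groups compared have fewer libraries for the variance. They gave 1533 for salt in CSR28 roots at 54 h and 8286 in CSR28 shoots at 6 h, and for the genotype difference 2186 and 67 in roots at 6 h and 54 h and 335 and 1494 in shoots. For the time difference they gave 603 in CSR28 roots and 3914 in CSR28 shoots, and for control plants 2322 in roots at 54 h and 3002 in shoots at 6 h.

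A minimum of 2-fold lowers counts by construction. It left 4738 and 4329 for salt in CSR28 roots, 8439 and 8913 in CSR28 shoots and 3621 and 9681 in IR28 shoots, at 6 h and 54 h. The genotype difference in shoots at 6 h kept 1259, the time differences in shoots 3695 (CSR28) and 4088 (IR28), and the control difference in shoots 4166 and 3380. Genes shared at 2-fold in one direction numbered 1678 and 2525 between genotypes in roots, 2689 and 6726 in shoots, at 6 h and 54 h. Between times they numbered 2132 in CSR28 roots, 1443 in IR28 roots, 4748 in CSR28 shoots and 2677 in IR28 shoots.

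Weights per library raised 16 counts, but the estimation stopped before it converged. Single libraries got extreme weights, 66.4 and 0.012 for replicates 2 and 1 of CSR28 root 54 h control and 592 and 0.056 for replicates 2 and 1 of CSR28 shoot 6 h control, and whether this raised the counts was not tested. They were 13006 and 15986 for salt in CSR28 roots, 8599 and 20965 in IR28 roots, 4993 and 14681 for the genotype difference in roots and 8664 and 2631 in shoots. Time differences gave 6872 and 14213 in roots and 12003 and 10408 in shoots (CSR28, IR28), and control differences 8184 and 17613 in roots and 17074 and 7979 in shoots.

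Without the libraries that stood apart the counts rose to 11006 and 6464 for salt in CSR28 and IR28 roots at 6 h, 2282 for the genotype difference in roots at 6 h, 2209 and 4823 for the time difference in CSR28 and IR28 roots, 6212 for control roots at 6 h and 1371 for the genotype difference in shoots at 54 h. It fell to 382 for the genotype difference in roots at 54 h. The histone list in the time difference of CSR28 roots reversed, from a median of -0.41 to 0.08 without CSR28 root 54 h control replicate 1 and likewise 0.08 without the libraries that stood apart, and its adjusted p went from 0.0119 to 0.594 and 0.555. The lowest median with 1 library left out was -0.83, without replicate 3 of the same group.

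Leaving out 1 library in turn kept the salt counts within 1.5 times, from 5452 to 6525 in CSR28 roots at 6 h and 13694 to 14110 in IR28 shoots at 54 h. The genotype difference was the least steady. In roots at 6 h it ranged from 251 (IR28 salt replicate 1) to 741, with 265, 272, 288, 292, 336, 358 and 391 for IR28 salt replicate 2, CSR28 control 1, CSR28 salt 2, IR28 control 2, IR28 control 3, CSR28 salt 3 and CSR28 control 3. In roots at 54 h it ranged from 284 (CSR28 salt 3) to 7301 (CSR28 control 3), with 299, 338, 351, 390, 432, 474 and 3038 for IR28 salt 2, IR28 control 2, IR28 control 3, IR28 control 1, CSR28 salt 2, CSR28 control 1 and IR28 salt 3. In shoots at 6 h it ranged from 943 (IR28 salt 3) to 6267 (CSR28 control 3), with 1055, 1200, 1233, 1301 and 1444 for CSR28 salt 3, IR28 control 1, CSR28 salt 2, IR28 control 2 and IR28 salt 2. Control roots at 54 h ranged from 4163 to 11576 (CSR28 control 3). The 3 libraries whose loss raised a count by more than 1.5 times were replicates whose trend with transcript length ran against that of the library that stood apart. Trends were taken against the sister libraries, so such opposite trends arise by construction and need not be a property of these replicates. The cause of the raised counts was not tested.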

Other observations

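Genes of chloroplast and iron nutrition gave further differences without salt. The root level of photosynthesis genes as a share of their shoot level had a median of 4.21% in CSR28 and 1.69% in IR28 at 6 h, and 3.17% and 1.49% at 54 h. For the small subunit gene RBCS2 it was 0.183% and 0.156% at 6 h. Iron uptake genes were higher in 5 of 7 in CSR28 control roots at 6 h (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.17e-04, adjusted p = 0.385 with an estimated correlation). Aquaporins were higher in 6 of 14 there (8 adjusted over the list alone, adjusted p = 4.17e-04, adjusted p = 0.428 with an estimated correlation), and histones in CSR28 control shoots at 6 h in 30 of 57 (34 higher and 2 lower adjusted over the list alone, adjusted p = 1.92e-07, adjusted p = 0.644 with an estimated correlation).

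The model LOC_Os07g05365, described as a photosystem II 10 kDa protein, rose in IR28 shoots at 54 h from 5.15 ± 2.74 to 1895 ± 427 scaled TPM (log2 fold 8.64, SE 0.38, adjusted p = 5.92e-14), against the direction of the photosynthesis list. The 10 genes with the highest values held from 2.81% to 14.5% of a library's total value.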
